A study of Mus musculus with 6 samples.

How the data were processed

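Total RNA of C2C12 myotubes, extracted with TRIzol and labelled with Cy3, was hybridised to a mouse circRNA array (Arraystar V2), one array per sample, 3 control and 3 CoCl2 samples, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The files from each array hold 15712 spots. The intensity values were made by the authors with Agilent Feature Extraction 11.0.1.1 in a 1-colour protocol, per the file headers. In each scanner file the processed signal is an intensity after background subtraction and detrending within the array, with no scaling between arrays. The grid file names the mouse build mm9, per the file headers, but no coordinates come with the probes. The deposited value table lists 11128 circRNA probes, and 100% of its intensity values equal the raw median spot intensity of the same array with a tolerance of 0. The deposited table is therefore neither background-subtracted nor scaled, and its array medians are 34.5, 40, and 41 in control and 54, 55, and 81.5 in CoCl2. The authors' rule for choosing those probes and any later normalization are not given in the sources used here. Other deposited values used were flags of 0 or 1 for spots well above background, saturated or outlying.

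Spots of Agilent's own controls, the 15 probes named as negative and the 14 named as circRNA controls by the array's designer were left out, as were outlier-flagged spots. The log2 processed signal was averaged over the spots of a probe, and each array's 75th percentile over the 14301 remaining probes was subtracted. A probe was tested where it was well above background on at least 3 of the 6 arrays, which held for 11086 probes. The difference between CoCl2 and control was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 6 arrays without covariates, and p-values were adjusted by the Benjamini-Hochberg method over the tested probes. Each log2 change is CoCl2 minus control. A background-subtracted signal near the floor makes the fold of dim probes less certain.

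The slide was inferred from the scan date that each file records, and no slide identifier was used. It was the only batch found in the files. By this, 5 arrays shared one slide, with 3 control and 2 CoCl2 arrays, and CoCl2 replicate 3 lay on another. The slide was therefore examined as a block and by leaving that array out, which are the same fit for the treatment effect here. The labels do not say that a replicate number marks a shared day, and the deviations of same-numbered arrays from their group means correlated at -0.01, -0.11 and 0.08 for numbers 1, 2 and 3, so the numbers were not treated as pairs.

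The main setting, the naming rule and most alternatives were fixed before the data were examined. The rule named, among called probes whose groups did not overlap, the 12 largest rises and 12 largest falls. Because no source used here names the probes, only the first 2 per direction are printed and the rest are given as ranges. For the same reason the 17 host gene lists that had been fixed, hypoxia, sarcomere and other cell type markers among them, and the comparison of circRNAs from one host gene were not run. The alternatives were other scalings, normexp background correction with an offset of 50, other filters on dim probes, the deposited value table, outlier spots kept, a replicate block, a trended robust prior, an ordinary test per probe, and each array left out. Normexp was applied to the median spot signal, because the scanner files used here carry no mean signal column. Raising the undetected values of the named probes to the lowest scaled signal well above background, and leaving them out, were added after the data were seen.

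Simulated data were drawn with the tested probes' own means and limma's moderated spreads, as independent normal noise without a detection floor. This setting favours limma's test, so its results can look better than real data would give. The pipeline was tested on these simulated data, in which 200 of 11086 probes were changed. It called 100% of the 100 probes changed by a log2 of 2 and 22% of the 100 changed by a log2 of 1, with 6 unchanged probes called. Changes near 2-fold can therefore be missed at this number of arrays when few probes change. In the data 23.9% of the tested probes passed, which makes the adjusted threshold less strict than in the simulation. The 22% is therefore not the sensitivity for these data.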

Results

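Circular RNAs (circRNAs) were profiled in myotubes of C2C12, a mouse myoblast line that fuses into myotubes in low-serum medium, here with 2% horse serum. One group of 3 cultures received no treatment and one group of 3 received 200 µM cobalt chloride (CoCl2) for 48 h. CoCl2 is a hypoxia-mimicking agent that stabilises HIF-1α by blocking its prolyl hydroxylation, and the series concerns its toxicity to these cells. Each RNA was hybridised to one 1-colour circRNA array carrying 14236 circRNA probes, whose names begin with ASCRP. The design describes the 3 experiments per group as independent. No file used here pairs these probes with a circRNA name, a host gene or a genomic position, so circRNAs are identified by probe, and none is assigned to a gene or chromosome.

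A larger part of the circRNA probes was detected on the CoCl2 arrays. The share well above background was 69.9% ± 3.63 (SD, n = 3) in control and 81.2% ± 3.996 (SD, n = 3) in CoCl2. Single control arrays had 66.0%, 70.7% and 73.1%, and single CoCl2 arrays had 77.0%, 81.6% and 84.9%. The median unscaled circRNA signal was 14.2 ± 2.85 intensity units (SD, n = 3) in control and 28.7 ± 7.97 (SD, n = 3) in CoCl2. For both measures every CoCl2 array lay above every control array, with an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 can give. The number of arrays limits the precision of every value below. No spot was saturated. CoCl2 replicate 3, the brightest array, had its own scan date and was taken to lie on a second slide. The other 5 arrays shared a scan date and were taken to share a slide.

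**Figure D1:**
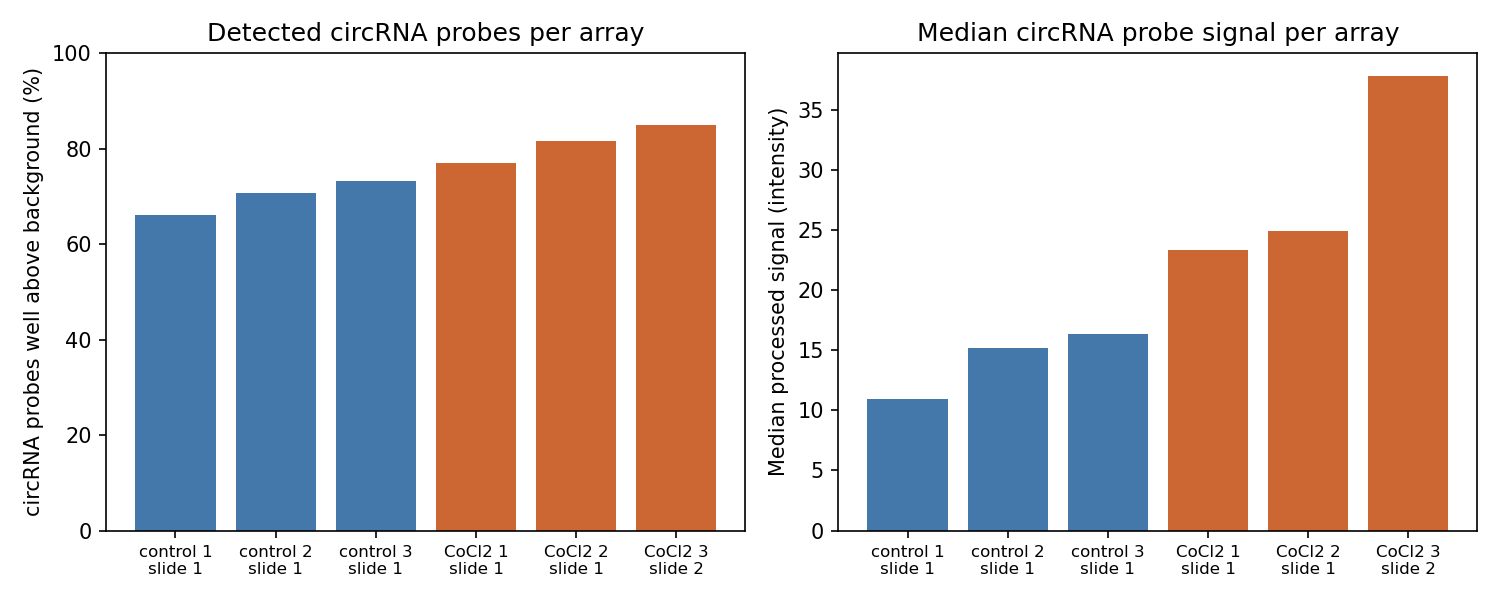
Bars give, for each array, the percentage of circRNA probes well above background (left) and the median processed signal of all circRNA probes in unscaled intensity units (right), with control arrays in blue and CoCl2 arrays in orange. Detection ranged from 66.0% to 73.1% on the control arrays and from 77.0% to 84.9% on the CoCl2 arrays.

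The comparison of CoCl2 with control asks which circRNAs differed after 48 h of exposure, once the arrays had been brought to one scale. The circRNA profile separated by treatment. Of 11038 circRNA probes tested, 1413 were higher and 1227 were lower in CoCl2 by limma's moderated test at a Benjamini-Hochberg adjusted p under 0.05. The median change was 2.24-fold among all probes called higher and 2.08-fold among all called lower. For these medians, 205 higher and 3 lower probes undetected in one group entered at an approximate lower bound of their fold. The counts of 1413 and 1227 describe change relative to each array's 75th percentile of signal, and not the total amount of circRNA.

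With the 34 catalogue and 14 custom probes that carry no circRNA prefix, 11086 probes were tested and 2655 (23.9%) passed, 1418 higher and 1237 lower. With those bounds, 2530 of the 2655 changed by at least 1.5-fold. With normexp background correction the calls past 1.5-fold numbered 1074 after quantile normalization and 1313 with the 75th percentile, by fitted change. In the main setting the smallest log2 change among the calls detected in both groups was 0.65. Detected in both groups means well above background on some, not necessarily all, arrays of each group. In total 4375 probes had an unadjusted p under 0.05. The 3 CoCl2 values lay wholly on one side of the 3 control values for 4974 probes (44.9%), against 10% by chance, and for 2646 of the 2655 called. Array profiles correlated at r of 0.949 to 0.976 within groups and 0.872 to 0.930 between groups, across probes, which are not independent replicates. The first principal component held 59.9% of the variance and placed the 3 control arrays apart from the 3 CoCl2 arrays.

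**Figure D2:**
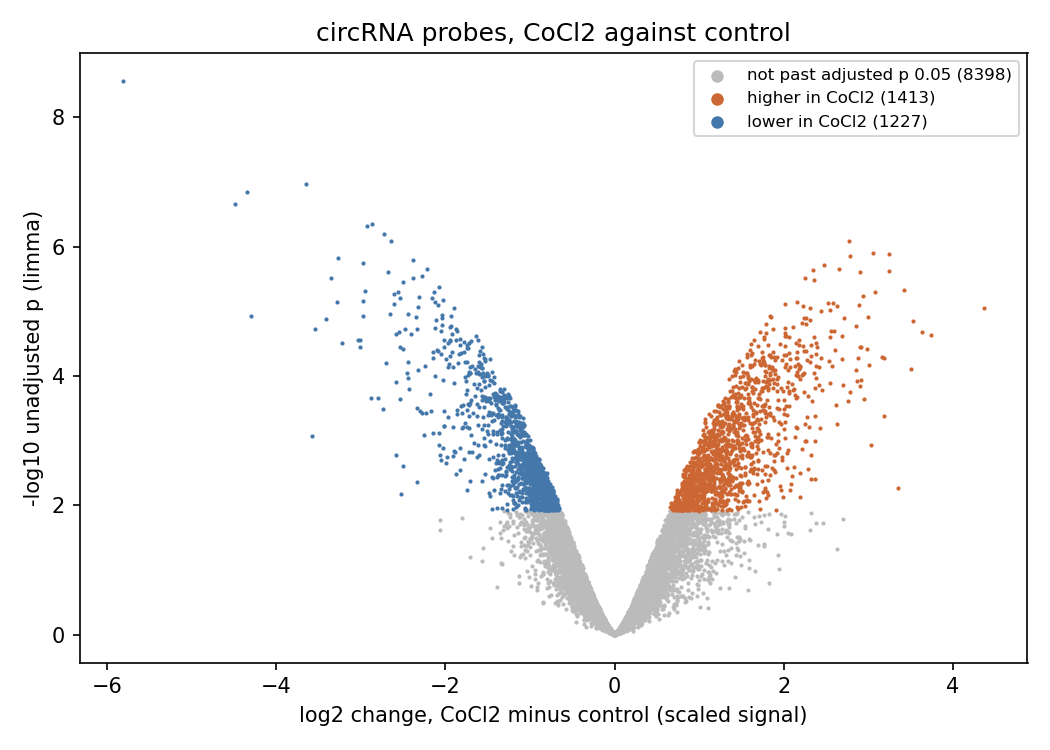
Each point is one tested circRNA probe, placed by its log2 change (CoCl2 minus control, signal scaled to each array's 75th percentile) and the -log10 of its unadjusted limma p, as fitted, including probes undetected in one group. Orange marks the 1413 probes higher in CoCl2, blue the 1227 lower, and grey those not past an adjusted p of 0.05.

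Large changes were present in both directions. With the bounds in place of fitted values, 920 called probes were higher and 706 lower by at least 2-fold, 117 higher and 98 lower by at least 4-fold, and 12 higher and 15 lower by at least 8-fold. The interquartile range of the 1213 higher calls detected in both groups lay between 0.99 and 1.56 on the log2 scale. That of the 1234 such lower calls lay between -1.34 and -0.89. Both sets include probes undetected on part of a group's arrays, whose fitted changes were kept here and in the fold counts. Among the 12 rises that the naming rule ranked first by fitted change, 9 were detected in both groups and spanned log2 changes of 3.19 to 4.37. The other 3 were well above background on no control array, with approximate lower bounds of 2.30-fold to 3.30-fold. The 12 falls spanned -3.23 to -5.82. Only 3 of those 12 rises were well above background on all 6 arrays, compared with 8 of those 12 falls.

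The largest fall was that of ASCRP4002119, from 4.21 ± 0.13 in control to -1.61 ± 0.36 in CoCl2 (mean ± SD of log2 signal minus the array's 75th percentile, n = 3 each). This was 56.3-fold lower, a log2 change of -5.82 (SE 0.25, limma adjusted p = 3.019e-05), and the probe was well above background on all 6 arrays. Its unscaled signal was 772 to 960 on the control arrays and 20.4 to 45.3 on the CoCl2 arrays. ASCRP4007793 fell from 0.86 ± 0.18 to -3.63 ± 0.62 (SD, n = 3 each), a log2 change of -4.49 (SE 0.32, limma adjusted p = 0.0006062). It was well above background on all 3 control arrays and on 1 CoCl2 array, so that its lower level was measured on a single array and the size of the fall is uncertain. The detected array was CoCl2 replicate 3, at -2.92, which lay on the second slide. With the other 2 CoCl2 values left out the log2 change was -3.78. These values, -4.02 and -3.94, already lay above the lowest scaled signal well above background of their arrays, -4.11 and -3.99. Raising them to it therefore changed nothing and is no check on the size of the fall.

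The largest fitted rise was that of ASCRP4005170, from -3.33 ± 1.03 in control to 1.05 ± 0.48 in CoCl2 (SD, n = 3 each). The log2 change was 4.37 (SE 0.48, limma adjusted p = 0.001768), and the probe was well above background on 2 of the 3 control arrays and on all 3 CoCl2 arrays. The value of control replicate 1 lay below the lowest scaled signal well above background on that array; raised to it, the change was 15-fold (log2 3.91), and with this value left out it was 13.8-fold (log2 3.78). ASCRP4003830, well above background on all 6 arrays, rose 13.4-fold from -1.16 ± 0.82 to 2.58 ± 0.72 (SD, n = 3 each), a log2 change of 3.74 (SE 0.47, limma adjusted p = 0.002453). Control replicate 1 gave the lowest value of both risen probes. The order of these rises depended on the background treatment: with normexp and quantile normalization the log2 changes were 1.71 for ASCRP4005170 and 2.47 for ASCRP4003830. Over all alternatives the log2 change ranged from 1.59 to 5.33 for ASCRP4005170, from 2.47 to 4.69 for ASCRP4003830, from -5.95 to -3.98 for ASCRP4002119 and from -4.84 to -1.60 for ASCRP4007793.

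**Figure D3:**
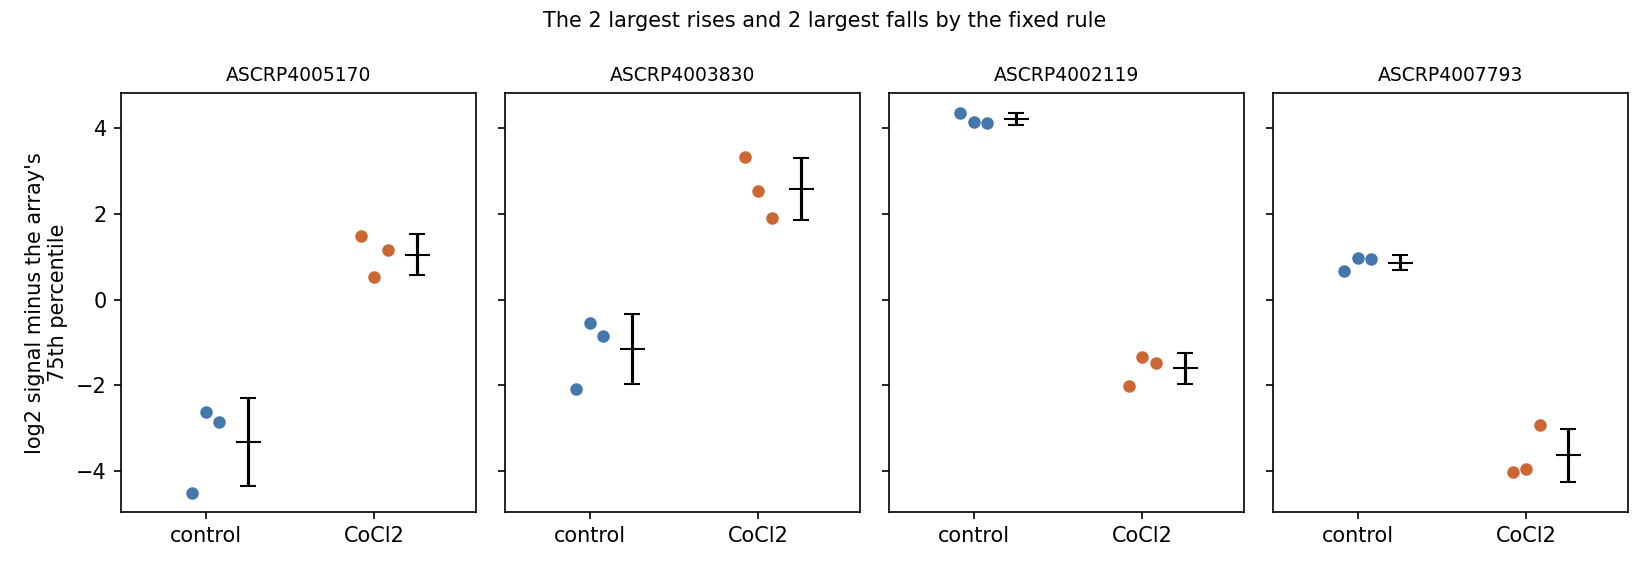
Points are the 3 arrays of each group for the 2 circRNA probes with the largest fitted rise and the 2 with the largest fitted fall, as log2 signal minus the array's 75th percentile; the bar beside them is the mean and SD. In each of the 4 probes the 3 CoCl2 values lie wholly on one side of the 3 control values.

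Some circRNAs crossed the detection limit. Of the tested probes, 429 were well above background on all 3 CoCl2 arrays and on no control array, and 3 showed the reverse. Of the 429, 205 were called higher, with a median of at least 1.29-fold and a highest value of at least 3.86-fold. For these bounds the control level was taken, per array, as the higher of the probe's own value and the lowest scaled signal well above background. The bounds are approximate, because an undetected value can lie above that lowest signal, as the undetected CoCl2 values of ASCRP4007793 did. For 42 of the 205 this bound was under 1, which gives no fold, and for 80 it was at least 1.5-fold. All 3 probes lost below background were called lower, by at least 2.56-fold to at least 4.26-fold. The CoCl2 arrays were brighter, and their lowest scaled signal well above background was -4.78 to -3.99, against -3.51 to -3.11 on the control arrays.

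Probes without a circRNA prefix were also called. Of the 34 catalogue probes tested, 3 were higher and 8 lower, and of the 14 custom probes 2 were higher and 2 lower, at the same adjusted threshold. With no scaling between arrays the split was 12 higher and 1 lower among the catalogue probes and 2 higher and 0 lower among the custom probes. No scaling leaves the shift shared by most probes in place. Among the catalogue probes, 1 was higher and 12 lower with normexp and the 75th percentile, and 2 higher and 1 lower with the ordinary test. Without control replicate 1 they had 2 higher and 2 lower. The custom probes again had 2 higher and 2 lower after quantile normalization and with the percentile over probes detected on all arrays. With median scaling they had 2 higher and 4 lower. With normexp background correction they had 0 higher and 2 lower after quantile normalization, and 0 higher and 5 lower with the 75th percentile. Of the 11 custom probes well above background on all 6 arrays, 0 were higher and 5 lower. The ordinary test per probe called 0 of the 14 custom probes. The rises called among the custom probes therefore depended on the background treatment, the detection filter and the test. What these probes detect is not given in the sources used here.

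Leaving out any 1 of 4 of the 6 arrays lowered the number of calls by more than 1.5 times. Fewer arrays lower the power of the test by themselves, whichever array is left out. The ordinary test per probe gave 1004 calls, and the fit without a filter on dim probes gave 1739. The balance of direction depended on the scaling, on the test and, under the 75th percentile scaling, on the background treatment. Leaving out one array gave 1454 calls without control replicate 1, 1606 without control replicate 2, 1652 without control replicate 3, 1432 without CoCl2 replicate 1, 2068 without CoCl2 replicate 2 and 2571 without CoCl2 replicate 3. The last is also the count within the shared slide and the count with the slide as a block, and 1077 probes (612 higher and 465 lower) passed in all 6 of these fits. Higher probes made up 53.4% of the calls. With the scaling alone changed this was 50.6% after quantile normalization, 54.7% with the percentile over probes detected on all arrays, 47.6% with median scaling (1301 higher and 1432 lower) and 98.0% with no scaling. With normexp background correction it was 28.2% with the 75th percentile and 49.4% after quantile normalization. Background treatment thus moved the balance with the 75th percentile, but hardly after quantile normalization. Whether the normexp offset under a single scaling factor per array produced the value of 28.2% was not tested. With the ordinary test per probe and the main scaling, higher probes made up 45.0% of the calls (452 higher and 552 lower). Which direction held the majority of calls is therefore not settled by these data. Requiring detection on all 6 arrays gave 44.9% (1219 higher and 1495 lower), but that filter does not settle this question. It removes dim probes undetected on the dimmer control arrays, and also some that fell below detection on CoCl2 arrays, such as ASCRP4007793. The main filter let in 429 probes detected on the CoCl2 arrays alone and 3 on the control arrays alone. Both filters can therefore shift the balance. Without scaling the median log2 change of the tested probes was 0.92, a shift that the 75th percentile scaling removed, leaving a median of -0.04.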

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

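The tests in this part were chosen after the data were seen. The array carries 14 probes that its designer named as circRNA controls, each printed in 10 spots, which the comparison left out, and all 14 were well above background on all 6 arrays. In the main limma fit 23.9% of the tested probes passed. When these 14 were added to that fit, 3 of them, a similar share, differed between the groups at an adjusted p under 0.05. One was higher in CoCl2 by 1.88 on the log2 scale (adjusted p = 0.00398), with a mean unscaled signal of 263 in control and 1728 in CoCl2. A second was higher by 1.30 (adjusted p = 0.00621), with 174 in control and 835 in CoCl2. The third had a log2 change of -1.02 (adjusted p = 0.0121), although its unscaled signal was 948 in control and 896 in CoCl2. What these 3 probes detect is not given in the sources used here, and no explanation for them was tested. The 14 ranged from -1.02 to 1.88 on the log2 scale, so they do not form a level reference for scaling these arrays.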

How the results depend on the processing

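The 4 named circRNA probes kept their direction and stayed past the threshold under every alternative that gave them a value. They were picked as the largest changes on these same arrays, so this is no independent support, and their fitted folds may be too large. The alternatives numbered 22 for ASCRP4002119 and ASCRP4003830 and 21 for ASCRP4005170 and ASCRP4007793. Among them, the slide block and leaving out CoCl2 replicate 3 are the same fit. The highest adjusted p, by the ordinary test per probe, was 0.0475. The sizes of the 4 changes moved more. In the order given, the smallest log2 changes were -3.98, 2.47, 1.59 and -1.60, against -5.82, 3.74, 4.37 and -4.49 in the main setting. Fold counts here use fitted changes, without the bounds for undetected probes. In the main setting 47.89% of the tested probes had a positive log2 change. Quantile normalization gave 2588 calls, median scaling 2733, of them 1301 higher and 1432 lower, and the percentile over probes detected on all arrays 2622, and 2298 of the 2655 calls passed under all 3, 1171 higher and 1127 lower. Adding both normexp settings left 1470, 582 higher and 888 lower, a split that takes in the lean of normexp with the 75th percentile. Normexp with the 75th percentile gave 4310 calls, 3094 of them lower, with 1313 past 1.5-fold and 28.53% of tested probes positive, and 8 of the calls changed direction. Normexp with quantile normalization left 1074 past 1.5-fold; adding an offset of 50 before the log shrinks the folds of dim probes by construction. Without a filter on dim probes 1739 passed, all beyond 1.5-fold, 940 higher and 799 lower; the cause was not tested. Requiring detection on all 6 arrays left 42.72% positive, with 1219 calls higher and 1495 lower. That filter itself removes dim probes that rose, and some that fell below detection. The deposited value table as given, which is not scaled, yielded 4605 calls, all beyond 1.5-fold, 4529 higher and 76 lower, with 93.8% positive. The ordinary t-test per probe, run as an alternative, gave 1004 calls after adjustment, 452 higher and 552 lower, 948 beyond 1.5-fold; it borrows no variance across probes. Of the alternatives added after seeing the data, no scaling gave 5005 calls, all beyond 1.5-fold, 4903 higher and 102 lower, with 91.99% positive, and the value table scaled to the 75th percentile gave 1984 lower calls and 32.36% positive. Leaving out one array gave 1432 to 2571 calls, each beyond 1.5-fold, with 768 to 1322 higher, 596 to 1249 lower and 46.69% to 50.73% positive. The replicate block, used although no label says that the numbers pair the arrays, gave 2138 calls. The host gene lists and the test of circRNAs of one host gene were not run. Signal near background limits the fold of dim probes.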

Other observations

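The tests of the overall signal and of the other splits were chosen after their results were seen; the tests of detection and of signal level were written before. Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 2655 probes and the highest of the others gave 0. Only 1 split, the real one, reached that count, and 10 splits are too few for a share under 0.05.

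The unscaled signal was higher on the CoCl2 arrays for 92.0% of the tested probes, by a median of 1.89-fold. Within the shared slide a scanner gain that differs between the groups is not expected, because its 5 arrays share a scan date. The comparison of negative spots there is therefore no separate evidence on gain. Above the dark offset the negative spots differed by 0.023 on the log2 scale, with a range of 0.367 between those 5 arrays. The median signal of the tested circRNA probes differed by 0.751. More labelled RNA on the CoCl2 arrays stays open, since the spike-in probes lay at 1.18 times the signal of the negative spots and so carry no reference. A rise of the whole circRNA population under CoCl2 also stays open, untested. These 2 explanations cannot be told apart here. The 1.89-fold shift also includes CoCl2 replicate 3 from the second slide, where a higher gain was not tested and stays open. That array's negative spots had a mean raw signal of 17.7, against 13.6 to 15.2 on the other arrays. The median raw signal of its spike-in probes was 23, against 16 to 18.

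Probes gained above background far outnumbered those lost, 429 against 3. With 1 common scaled signal threshold on all arrays, 136 probes were gained and 105 lost, a ratio of 1.3. The excess of gains may therefore come from the brighter CoCl2 arrays, which detect dimmer probes, and a gain of circRNA species is not needed for it. With each control array's lowest scaled signal well above background, 80 gained probes had an approximate bound of at least 1.5-fold.

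With the 75th percentile scaling, dim probes leaned higher and bright probes lower in CoCl2. The tested probes were ranked by mean signal into 5 equal classes. In the dimmest class 308 were called higher and 162 lower, and in the brightest 285 and 339, and the median log2 change differed by 0.268 between these classes. Among probes well above background on all 6 arrays the difference was -0.03, with 112 higher and 274 lower in the dimmest class. That value decides nothing about the filter as a cause, because this filter selects on the change itself. It removes dim probes undetected on the dimmer control arrays, and also some that fell below detection on the CoCl2 arrays. After quantile normalization the lean in the calls was gone, with 220 higher and 207 lower in the dimmest class and 316 and 288 in the brightest, while the difference of the medians fell to 0.102. How much a single scaling factor per array contributes stays open, since quantile normalization gives every array the same distribution and can remove a true level-dependent change as well.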
